A study of Homo sapiens with 6 samples.

How the data were processed

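The samples were 6 RNA libraries of the human cell line A673, 3 labelled parental control and 3 labelled EWS-FLI1 knockout. Per the labels' protocols, polyadenylated RNA was enriched with oligo-dT beads, libraries were made with the NEBNext Ultra II RNA kit and sequenced on an Illumina NovaSeq. The labels do not state a strand-specific protocol, so reads of overlapping and antisense genes may not be told apart here. The authors deposited a single table of estimated counts per gene, with 1 column per library and 62700 rows. Per the submitters' processing notes, kallisto 0.48.0 and the build hg38 were used. How transcripts were summed to genes, the annotation release, trimming and filters are not given in the sources used here. kallisto assigns reads to transcripts by likelihood and splits reads that fit several, so genes with near-identical copies are uncertain. Between 53.3% and 56.6% of the values in a column were whole to within 1e-06. Of the rows, 20357 carried only an identifier as name. Some symbols stand on several rows with identical counts, as genes shared by the X and Y chromosomes do: 25 tested symbols stood on 62 such rows. In gene lists each symbol was counted once. CD99, among the activated targets, is such a gene.

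The estimated counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 28485. Libraries were scaled by TMM factors, and a quasi-likelihood model with robust dispersions and genotype as its only term was fitted to all 6 libraries. Tests were two-sided with Benjamini-Hochberg adjustment over all tested genes at 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. The biological coefficient of variation was 7.53%. A floor of 3 counts corresponds to between 0.00752 and 0.0117 CPM in a library. Counting error is thus small for genes of several CPM, and replicate spread sets the precision. Reads without molecular identifiers are not independent molecules, so this floor covers counting error only.

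Gene lists were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over 42 lists, and again with a correlation estimated for each list and with fry. camera compares a list with all other genes; fry asks whether the genes of a list move, on balance, in 1 direction. At the preset correlation 22 lists were called, 11 higher and 11 lower. With an estimated correlation the call of the activated targets held and the other 21 were lost. fry called 39 lists. The lists covered known targets of EWS-FLI1, matrix, adhesion, signalling, splicing, proliferation, metabolic and stress genes, markers of other cell lineages, and genes that reflect library composition (mitochondrial, ribosomal and histone genes).

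The groups, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The rule took EWSR1 and FLI1, the 10 largest rises and 10 largest falls among named genes of at least 5 CPM on average with non-overlapping groups, up to 4 members with the smallest adjusted p from each list, and every FET or ETS member of at least 1 CPM, 199 genes in all. The planned tests of transcripts and of transcript usage need counts per transcript. The table holds counts per gene, so these tests were not run, and gene levels of splicing factors are the splicing-related values reported.

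Replicates were compared before averaging. Over genes with at least 100 counts in a pair of libraries, the chi-square per degree of freedom lay between 11.1 and 78.1, so no pair of libraries within a genotype agreed within sampling noise. The genotypes share replicate numbers, and the main model has no term for them.

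The same steps were tested on simulated counts for this comparison, drawn for the 28485 genes from the means and sizes of these libraries. Of 50 genes each, 34% were recovered at a simulated fold of 1.2, 78% at 1.5, 84% at 2 and 100% at 4, and 21 of 28285 unchanged genes were called. The true calls numbered 17, 39, 42 and 50, so the 21 false calls made up more than a 0.05 share of all calls. Only these few genes were changed in the simulation, against 73.8% called in the data. How the scaling behaves under such a broad change was therefore not tested. A list that was raised was called higher, and 0 of 40 random lists were called. Simulated genes were drawn independently of each other, while the lists tested here had estimated correlations of up to 0.863. The simulation thus cannot show how often lists of correlated genes are called falsely.

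Alternatives covered other scalings (DESeq2 size factors, total count only, upper quartile), other filters on low counts, thinning to the smallest library, unrounded counts, the DESeq2 1.42.0 Wald test, limma-voom, glmTreat, a term for the replicate number, and leaving out each library. Subtraction of the share described for abundant genes and removal of the genes of shifted chromosome windows were added after the data were seen. Gene positions and types came from GENCODE release 29 on GRCh38, matched by gene identifier without its version for 92.5% of tested genes, and they may differ from the annotation behind the counts. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.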

Results

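RNA was sequenced from A673, a cell line grown from a Ewing sarcoma and driven by EWS-FLI1, a fusion of the RNA-binding protein EWSR1 with the ETS transcription factor FLI1. The series compared 3 parental libraries with 3 libraries labelled as EWS-FLI1 knockout, and its stated interest was how the fusion affects alternative splicing. The values were estimated counts per gene, so the comparison covers gene levels and not isoforms. Totals ranged from 301605666 to 342624492 estimated counts per library, with a mean of 333173651 ± 9282513 in parental and 305029729 ± 4760055 in knockout libraries (SD, n = 3 each). At least 10 counts were held by 28347 ± 161 genes in parental and 26163 ± 361 genes in knockout libraries (SD, n = 3). In what follows, levels are TMM-normalised CPM as mean ± SD of the 3 libraries of a genotype, and each log2 fold change is knockout over parental with the standard error (SE) of the edgeR quasi-likelihood fit. The labels do not say that replicates were separate cultures or clones, so p-values measure the spread between these libraries, which may be technical. Nor do they say whether the knockout is 1 clone or a pool, so for every gene a difference between clones cannot be separated from the loss of the fusion.

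The fusion partners were examined in every library. EWSR1, on chromosome 22 from 29268009 to 29300525 (GRCh38), held 300.0, 288.2 and 290.7 CPM in the parental libraries and 240.6, 252.0 and 242.0 CPM in the knockout libraries. Its level fell with a log2 fold change of -0.26 (SE 0.047, edgeR adjusted p = 3.81e-05), and all 3 knockout libraries lay below all 3 parental ones. FLI1, on chromosome 11 from 128686535 to 128813267, held 39.6, 41.9 and 40.6 CPM in parental and 53.7, 54.8 and 50.8 CPM in knockout libraries. Its log2 fold change was 0.38 (SE 0.050, edgeR adjusted p = 4.27e-07) with every knockout library above every parental one, but -0.04 when libraries were scaled by total count only. A count per gene adds the reads of the fusion transcript to those of the normal EWSR1 and FLI1 transcripts, so neither value checks whether the fusion was lost, and the known target genes below are what bears on the labels.

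**Figure D1:**
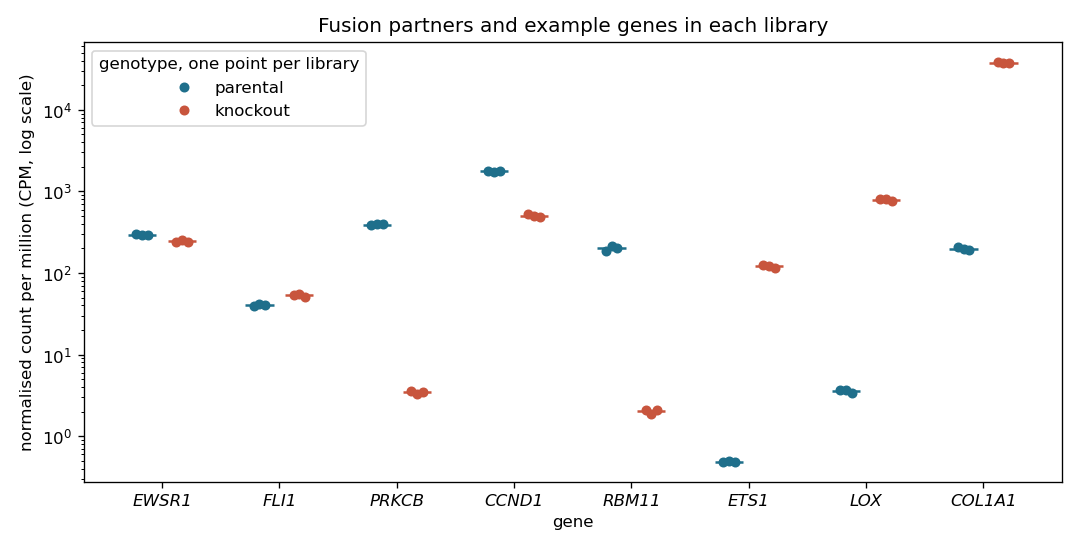
Normalised CPM (log scale) of 8 genes in each of the 6 libraries, with 1 point per library and a line at the mean of the 3 libraries of a genotype. FLI1 stays between 39.6 and 54.8 CPM in all 6 libraries, while PRKCB, CCND1 and RBM11 are lower and ETS1, LOX and COL1A1 higher in each knockout library than in any parental one.

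The genotypes differed across most of the transcriptome. COL1A1, the main chain of type I collagen, took 0.0231% ± 0.000697 of all counts in parental and 3.27% ± 0.0668 in knockout libraries (SD, n = 3), and all collagen genes together took 0.192% ± 0.00546 and 6.92% ± 0.0766. Among 28485 tested genes, 10328 rose and 10687 fell at an edgeR adjusted p under 0.05, 73.8% of those tested, and 7470 did not pass. A log2 fold change beyond 1 was reached by 6205 of the risen and 5775 of the fallen genes, and 5153 rose and 4412 fell when the test itself was made against a log2 fold change of 1. The groups did not overlap in 76.7% of the tested genes, where chance gives 10% for 3 against 3. This split depends on the scaling: with total counts only, 7370 genes rose and 14949 fell, so that risen genes made up 33.0% of the calls in place of 49.1%, and the median of all genes moved by -0.42 on the log2 scale. Upper quartile factors moved that median by -0.20, with 8702 risen and 12780 fallen genes, or 40.5% risen.

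The largest rises among named genes of at least 5 CPM on average were those of SLC7A4 and MOXD1. SLC7A4, a member of a cationic amino acid transporter family, had a log2 fold change of 9.47 (SE 0.10) to 26.0 ± 0.826 CPM, and MOXD1 one of 8.22 (SE 0.099). VEGFC, a growth factor of lymphatic vessels, rose by 8.11 (SE 0.080) to 79.1 ± 2.39 CPM. The matrix proteins POSTN (periostin) and LUM (lumican) rose by 8.08 (SE 0.070) and 8.03 (SE 0.078), and periostin reached 5026 ± 304 CPM. PDCD1LG2, which encodes the PD-1 ligand PD-L2, rose by 8.02 (SE 0.089), and TEK, the angiopoietin receptor, by 8.02 (SE 0.087). MAMDC2 and ADAMTS12 changed by 8.09 (SE 0.067) and 8.02 (SE 0.089). LIF-AS2, at 8.10 (SE 0.22), lies antisense to LIF. As the labels do not state strand, its reads may not be told apart from those of LIF where both overlap, which was not measured.

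The largest falls among named genes of at least 5 CPM on average were those of CPNE4, with a log2 fold change of -7.01 (SE 0.11), and of POU1F1. POU1F1, a pituitary transcription factor, went from 130.3 ± 6.68 to 1.02 ± 0.114 CPM (-7.00, SE 0.079). ASIC2, an acid-sensing ion channel, changed by -7.00 (SE 0.11), TRDN, the muscle protein triadin, by -6.99 (SE 0.11), and MYH2, a skeletal muscle myosin heavy chain, by -6.93 (SE 0.088). CLVS2 went from 165.3 ± 5.88 to 1.37 ± 0.0187 CPM (-6.92, SE 0.065), with SHISA6 at -6.92 (SE 0.086), LINC03018 at -6.90 (SE 0.13), SERTM1 at -6.90 (SE 0.075) and OLFM3 at -6.90 (SE 0.071). Among abundant genes, the lowest shares of raw counts kept in the other genotype were alike in both directions. Of 3990 genes with a mean of at least 20000 raw counts in parental libraries, the 20 with the lowest knockout share kept a median of 0.617% of the parental count. Of 3251 such genes in knockout libraries, the 20 lowest kept a median of 0.586% in parental libraries. Within 2 times these shares lay 157 fallen and 180 risen genes of at least 5000 counts, and those of at least 20000 counts had median log2 fold changes of -6.63 and 7.61. SLC7A4, at a mean of 6866 counts in knockout libraries, kept less, 0.208%. A lower level given in any paragraph for a gene with a fold change near or beyond the medians of -6.63 and 7.61 may hold such a share. The SD and SE of that gene do not cover it.

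**Figure D2:**
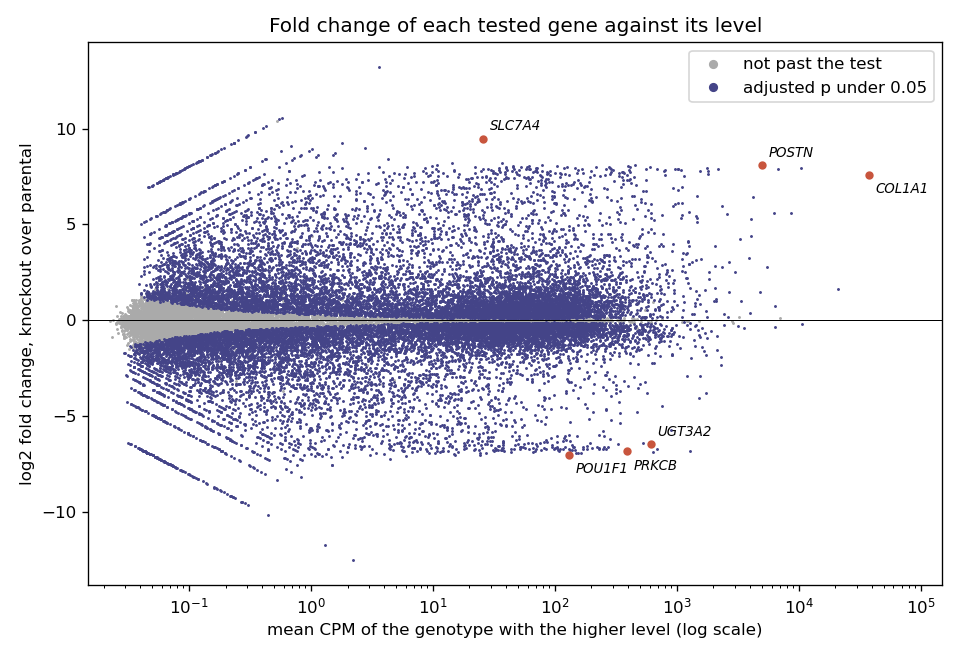
Log2 fold change (knockout over parental) of each tested gene against the mean CPM of the genotype in which it was higher (log scale), with 1 point per gene, blue past an adjusted p of 0.05 and grey otherwise. Abundant genes end in a sharp lower edge near POU1F1 (-7.00) and an upper edge near POSTN (8.08), SLC7A4 (9.47) lies beyond it, and genes of a few counts fan out at the left.

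Genes known to be activated by EWS-FLI1 were lower and genes known to be repressed by it were higher in the knockout libraries. Of 42 activated targets 37 fell, 1 rose and 4 did not pass, with a median log2 fold change of -3.10 and quartiles of -6.38 and -1.59. The list was called lower by camera (adjusted p = 4.01e-40) and also with the correlation between genes estimated from the data (adjusted p = 0.0418), the 1 list of 42 for which that held. PRKCB, a protein kinase C that Ewing sarcoma cells depend on, fell from 393 ± 4.09 to 3.46 ± 0.150 CPM (-6.83, SE 0.063). UGT3A2, CYP4F22 and PPP1R1A changed by -6.44 (SE 0.063), -6.70 (SE 0.066) and -6.71 (SE 0.068). Of 23 repressed targets 21 rose and 2 fell, with a median of 5.35 (camera adjusted p = 1.11e-38, adjusted p = 0.086 with an estimated correlation). LOX, the lysyl oxidase that cross-links collagen, rose from 3.57 ± 0.187 to 794 ± 32.7 CPM (7.80, SE 0.069), and THBS1 (thrombospondin 1) rose by 7.89 (SE 0.071). The knockout level of PRKCB and the parental level of LOX may hold the share that abundant genes keep in the other genotype. CCN2, a matricellular growth factor, rose by 7.06 (SE 0.061) and NT5E, the ecto-nucleotidase CD73, by 7.74 (SE 0.072). With p-values adjusted over the list alone, 37 activated targets fell and 1 rose, and 21 repressed targets rose and 2 fell. Both lists were written from general knowledge of Ewing sarcoma, in which A673 is a common model, and not from these libraries.

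**Figure D3:**
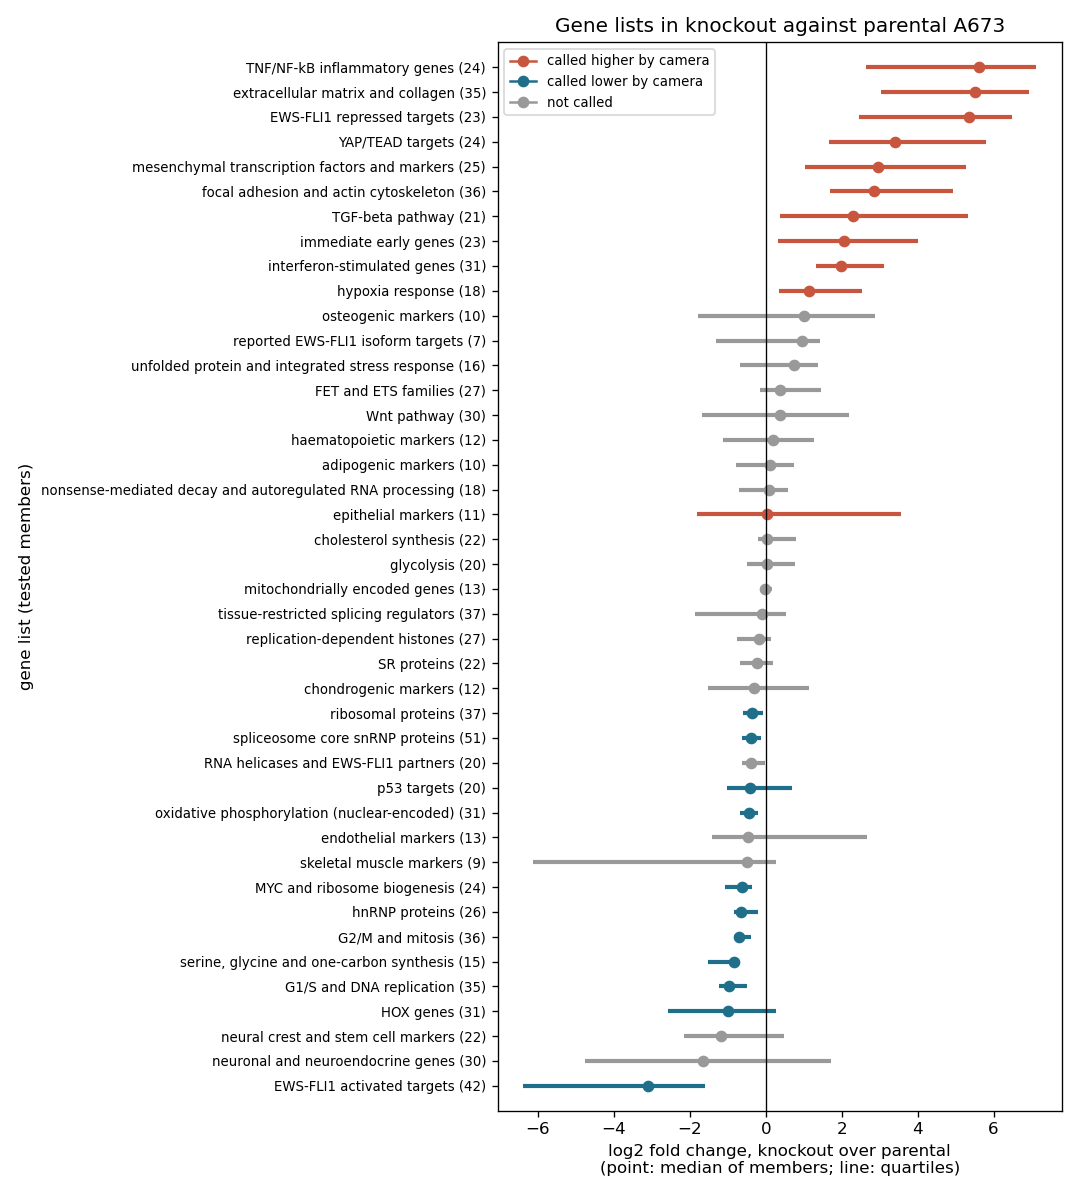
Median log2 fold change (point) and quartiles (line) of the tested members of the 42 gene lists, with the number of tested members in parentheses and the colour showing the camera call at the preset correlation. Activated targets lie lowest at -3.10, and inflammatory, matrix and repressed target genes lie highest at 5.62, 5.52 and 5.35.

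Extracellular matrix, adhesion and mesenchymal genes were higher in the knockout libraries. Of 35 matrix and collagen genes 32 rose and 2 fell, with a median log2 fold change of 5.52 (camera adjusted p = 5.31e-56, adjusted p = 0.086 with an estimated correlation). COL1A1 rose from 199 ± 8.13 to 37831 ± 260 CPM (7.57, SE 0.062), COL1A2 from 42.2 ± 1.49 to 10480 ± 348 CPM (7.96, SE 0.065) and COL3A1 from 28.6 ± 1.10 to 6792 ± 270 CPM (7.89, SE 0.066). These parental levels may hold the share that abundant genes keep in the other genotype. Of 25 mesenchymal transcription factors and markers 20 rose and 4 fell, with a median of 2.94 (camera adjusted p = 1.33e-19, adjusted p = 0.115 with an estimated correlation). The transcription factors PRRX1 and FOXC2 rose by 7.22 (SE 0.071) and 7.97 (SE 0.076), the collagen receptor ITGA11 by 7.81 (SE 0.071), and the hyaluronan receptor CD44 by 7.89 (SE 0.073). Of 36 focal adhesion and actin genes 35 rose and none fell, with a median of 2.85 (camera adjusted p = 9.77e-40, adjusted p = 0.086 with an estimated correlation). The actin-binding proteins TAGLN and CALD1 rose by 6.81 (SE 0.061) and 6.91 (SE 0.062), the integrin ITGA3 by 6.97 (SE 0.063), and PARVA, which links integrins to actin, by 6.90 (SE 0.065). Of 24 targets of YAP and TEAD, the effectors of the Hippo pathway, 23 rose and 1 fell, with a median of 3.40 (camera adjusted p = 4.45e-31, adjusted p = 0.086 with an estimated correlation). CCN1 rose by 5.79 (SE 0.058) and TGFB2 by 7.96 (SE 0.079), and CCN2 and NT5E are shared with the repressed targets. These counts, adjusted over the list alone, were 33 risen and 2 fallen matrix genes, 20 and 4 mesenchymal genes, 35 and 0 adhesion genes, and 23 and 1 YAP and TEAD targets.

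Since splicing was the stated interest, genes of the splicing machinery were described by class. Of 26 hnRNP proteins, which bind nascent RNA and often repress exons, 21 fell and 5 rose, with a median log2 fold change of -0.66 (camera adjusted p = 0.0124, adjusted p = 0.677 with an estimated correlation). HNRNPAB fell from 286 ± 9.09 to 126 ± 5.40 CPM (-1.18, SE 0.050), and RBMX, HNRNPA2B1 and HNRNPC changed by -1.10 (SE 0.050), -0.91 (SE 0.048) and -0.90 (SE 0.050). Of 51 core proteins of the spliceosome's small nuclear ribonucleoproteins 38 fell, 4 rose and 9 did not pass, with a median of -0.38 (camera adjusted p = 0.0117, adjusted p = 0.616 with an estimated correlation). SLU7, a factor of the later splicing step, changed by -1.31 (SE 0.052), the U1 protein SNRPA by -1.13 (SE 0.050), the Sm protein SNRPD3 by -0.92 (SE 0.050) and the recycling factor SART3 by -0.87 (SE 0.047). Of 22 SR proteins, which mostly promote exon inclusion, 14 fell and 6 rose, with a median of -0.24 that did not pass (camera adjusted p = 0.133) except with total counts only (adjusted p = 0.0155, median -0.667) and with no filter on low counts (adjusted p = 0.0434, median -0.271). Over the settings tried, fry and an estimated correlation included, that adjusted p ranged from 9.64e-05 to 0.616. SRSF12 changed by -5.21 (SE 0.088), and TRA2A and TRA2B by -0.94 (SE 0.050) and -0.86 (SE 0.047). SRSF8 changed by -1.17 (SE 0.057), with reads that can be shared with its parent gene SRSF2. Adjusted over the list alone, 21 hnRNP genes fell and 5 rose, 41 core genes fell and 4 rose, and 14 SR genes fell and 6 rose.

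Splicing regulators that are restricted to certain tissues moved in both directions. Of 37 such genes 17 fell, 12 rose and 8 did not pass, with a median of -0.11 and quartiles of -1.87 and 0.54 (camera adjusted p = 0.144). RBM11, also among the activated targets, fell from 200.8 ± 12.01 to 2.02 ± 0.141 CPM (-6.63, SE 0.072), and the neural stem cell regulator MSI1 by -3.71 (SE 0.077). RBM24, a regulator of muscle exons, rose from 0.134 ± 0.0159 to 12.9 ± 0.794 CPM (6.59, SE 0.11), and RBPMS rose by 2.28 (SE 0.053). Of 20 RNA helicases and reported partners of EWS-FLI1 14 fell and 5 rose, with a median of -0.40 and a mean of 0.03 (camera adjusted p = 0.449). The chromatin remodelling subunit SMARCC1 changed by -1.68 (SE 0.050) and the RNA polymerase II subunit POLR2G by -0.996 (SE 0.049), while the transcription factor RUNX1 rose by 7.35 (SE 0.092) and the remodelling subunit ARID1B by 1.03 (SE 0.055). Of 7 genes whose isoforms are reported to respond to EWS-FLI1, 4 rose and 3 fell in total gene level, with a median of 0.95 and a mean of -0.52 (camera adjusted p = 0.960). TERT, the telomerase catalytic subunit, changed by -6.85 (SE 0.14) and the cyclin CCND1 by -1.80 (SE 0.049), while PPFIBP1 rose by 2.06 (SE 0.056). Of 18 genes of nonsense-mediated decay and autoregulated RNA processing 8 rose and 8 fell, with a median of 0.08 and a camera direction of lower (adjusted p = 0.926). The decay factors UPF3A and UPF3B changed by -1.30 (SE 0.051) and -1.21 (SE 0.054), and SMG6 and GADD45B rose by 0.92 (SE 0.050) and 2.60 (SE 0.061). When adjusted over the list alone, the numbers of risen and fallen genes were 12 and 17, 5 and 14, 4 and 3, and 8 and 8 in the order of these lists. How exons were used within these or other genes was not analysed here.

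Members of the families of both fusion partners differed in direction. ETS1, the neighbour of FLI1 on chromosome 11, rose from 0.485 ± 0.00425 to 120 ± 5.69 CPM (7.95, SE 0.072), while FEV, an ETS factor of serotonergic neurons, fell from 38.1 ± 3.04 to 0.339 ± 0.0430 CPM (-6.81, SE 0.092). The parental level of ETS1 and the knockout level of FEV may hold the share that abundant genes keep in the other genotype. TAF15, a relative of EWSR1, changed by -0.67 (SE 0.054). Of 27 FET and ETS genes 16 rose, 7 fell and 4 did not pass, over all genes and adjusted over the list alone, with a median of 0.38 (camera adjusted p = 0.0883, and median -0.04 with total counts only). The list passed with no filter on low counts (adjusted p = 0.0102), without knockout replicate 3 (adjusted p = 0.0495) and with a term for the replicate number (adjusted p = 0.0452), within a range from 3.19e-05 to 0.635 over the settings tried. ELF3 rose by 5.40 (SE 0.12), ELF4 by 2.24 (SE 0.053), ETS2 by 1.49 (SE 0.047), ETV4 by 1.44 (SE 0.051), ETV6 by 1.18 (SE 0.051), ELK4 by 1.06 (SE 0.056), ELK3 by 0.81 (SE 0.049) and ELF1 by 0.67 (SE 0.051). GABPA and ETV3 changed by -0.51 (SE 0.056) and -0.25 (SE 0.052), and ETV2, near 1 CPM, by -0.64 (SE 0.13). ETV5 at 0.41 (SE 0.049), ELK1 at 0.36 (SE 0.048) and ELF2 at 0.18 (SE 0.053) rose with the main scaling and had values below 0 with total counts only, where ELF2 passed as lower (adjusted p = 0.000527). ETV1 and ERF, at 0.08 (SE 0.052) and 0.05 (SE 0.054), did not pass; both passed as lower with total counts only (adjusted p = 1.78e-05 and 1.62e-05) and with upper quartile factors (adjusted p = 0.0277 and 0.0166). ETV1 passed as higher without knockout replicate 3 (0.13, adjusted p = 0.0346) and ERF without parental replicate 1 (0.14, adjusted p = 0.00849).

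Genes of proliferation and of the making of ribosomes were lower in the knockout libraries. Of 35 genes of the G1/S transition and DNA replication 31 fell and 1 rose, with a median log2 fold change of -0.98 (camera adjusted p = 5.82e-07, adjusted p = 0.420 with an estimated correlation). The primase PRIM1 changed by -2.18 (SE 0.059), the ligase LIG1 by -1.76 (SE 0.050), the helicase cofactor CDC45 by -1.68 (SE 0.049) and thymidylate synthase, TYMS, by -1.58 (SE 0.047). Of 36 genes of G2/M and mitosis 30 fell and 4 rose, with a median of -0.70 (camera adjusted p = 0.000725, adjusted p = 0.616 with an estimated correlation). TOP2A, the mitotic topoisomerase, fell from 478 ± 28.8 to 185 ± 9.27 CPM (-1.37, SE 0.055), CDC25C by -1.95 (SE 0.055), HMMR by -2.08 (SE 0.058) and NEK2 by -1.32 (SE 0.052). Of 24 genes of MYC and ribosome biogenesis 20 fell and 2 rose, with a median of -0.64 (camera adjusted p = 0.00183, adjusted p = 0.488 with an estimated correlation). The nucleolar proteins NPM1, FBL and NCL changed by -1.76 (SE 0.052), -1.46 (SE 0.050) and -1.40 (SE 0.050), and MYCN went from 2.33 ± 0.289 to 0.0755 ± 0.0169 CPM (-4.93, SE 0.18). Of 37 ribosomal protein genes 27 fell and 6 rose, with a median of -0.35 (camera adjusted p = 0.0309, adjusted p = 0.821 with an estimated correlation), and their share of all counts was 4.55% ± 0.106 in parental and 2.62% ± 0.0418 in knockout libraries (SD, n = 3). RPL23 and RPL19 changed by -1.33 (SE 0.048) and -1.28 (SE 0.051), RPL5 by -0.80 (SE 0.049) and RPS4X by -0.74 (SE 0.047). Ribosomal protein genes and NPM1 have near-identical pseudogenes that share reads, so their levels are uncertain. Adjusted over the list alone, the numbers of fallen and risen genes were 31 and 1, 31 and 4, 20 and 2, and 27 and 6 in the order of these lists.

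Inflammatory, interferon, TGF-beta and immediate early genes were higher in the knockout libraries, while Wnt pathway genes moved both ways. Of 24 genes of the TNF and NF-kB response 23 rose and 1 fell, with a median log2 fold change of 5.62 (camera adjusted p = 6.31e-38, adjusted p = 0.086 with an estimated correlation). The chemokines CXCL8 and CCL2 rose by 7.65 (SE 0.067) and 7.98 (SE 0.074), to 284 ± 10.6 and 411 ± 24.5 CPM, the adhesion molecule ICAM1 by 6.49 (SE 0.064) and TNFAIP2 by 6.94 (SE 0.072). Of 31 interferon-stimulated genes 27 rose and 2 fell, with a median of 1.98 (camera adjusted p = 3.66e-14, adjusted p = 0.086 with an estimated correlation). HLA-B, a class I antigen whose reads can be shared with other class I genes, rose by 5.95 (SE 0.062), the immunoproteasome subunits PSMB8 and PSMB9 by 4.68 (SE 0.057) and 6.19 (SE 0.072), and the transcription factor IRF1 by 5.43 (SE 0.059). Of 21 TGF-beta pathway genes 17 rose and 4 fell, with a median of 2.29 (camera adjusted p = 7.42e-16, adjusted p = 0.164 with an estimated correlation), among them BMP4 with 7.97 (SE 0.068), LTBP2 with 7.81 (SE 0.070) and TGFBI with 7.30 (SE 0.067). Of 23 immediate early genes 18 rose and 4 fell, with a median of 2.06 (camera adjusted p = 5.98e-10, adjusted p = 0.267 with an estimated correlation). JUN rose by 4.74 (SE 0.059), FOSL2 by 7.34 (SE 0.064), IER3 by 5.35 (SE 0.059) and the phosphatase DUSP4 by 5.26 (SE 0.062). Of 30 Wnt pathway genes 17 rose and 12 fell, with a median of 0.37, and -0.06 with total counts only (camera adjusted p = 0.926). DKK3 and the ligand WNT11 rose by 7.87 (SE 0.070) and 6.90 (SE 0.088), while the receptor FZD4 and DKK2 changed by -5.37 (SE 0.058) and -4.39 (SE 0.054). Adjusted over the list alone, the numbers of risen and fallen genes were 23 and 1, 27 and 2, 17 and 4, 18 and 4, and 17 and 12 in the order of these lists.

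Metabolic and stress genes moved in part. Of 15 genes of serine, glycine and one-carbon synthesis 14 fell and 1 rose, with a median log2 fold change of -0.85 (camera adjusted p = 0.00184, adjusted p = 0.427 with an estimated correlation). Asparagine synthetase, ASNS, changed by -1.84 (SE 0.051), MTHFD2 by -1.74 (SE 0.050) and PSAT1 by -1.63 (SE 0.049), and the gene that rose was ALDH1L2, by 5.57 (SE 0.10). Of 31 nuclear genes of oxidative phosphorylation 27 fell and 4 rose, with a median of -0.45 (camera adjusted p = 0.0157, adjusted p = 0.704 with an estimated correlation). ATP5F1B changed by -1.09 (SE 0.048), CYC1 by -1.15 (SE 0.053), NDUFS3 by -1.05 (SE 0.049) and NDUFB8 by -0.99 (SE 0.052). Of 18 hypoxia genes 14 rose and 2 fell, with a median of 1.13 (camera adjusted p = 1.1e-07, adjusted p = 0.267 with an estimated correlation). Besides LOX these were led by adrenomedullin, ADM, with 6.85 (SE 0.070), the collagen hydroxylase P4HA2 with 5.96 (SE 0.061) and NDRG1 with 3.75 (SE 0.053). Of 20 p53 targets 12 fell and 7 rose, with a median of -0.43 (camera adjusted p = 0.0309, adjusted p = 0.413 with an estimated correlation), a call that a term for the replicate number ended (adjusted p = 0.0714). GDF15, FDXR, SESN2 and CCNG1 changed by -4.62 (SE 0.067), -2.76 (SE 0.065), -2.08 (SE 0.051) and -1.87 (SE 0.054); GDF15 and SESN2 are also known to answer the integrated stress response. Adjusted over the list alone, the numbers of risen and fallen genes were 1 and 14, 4 and 27, 14 and 2, and 7 and 12 in the order of these lists.

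Further lists were not called. Of 16 genes of the unfolded protein and integrated stress responses 10 rose and 6 fell, with a median of 0.74 (camera adjusted p = 0.303). The chaperone HSPA5 and the transcription factor CREB3L1 rose by 2.23 (SE 0.050) and 4.31 (SE 0.059), and TRIB3 changed by -3.61 (SE 0.055). Of 20 glycolysis genes 9 rose and 9 fell, with a median of 0.02 and a camera direction of lower (adjusted p = 0.926). The glucose transporter SLC2A1 rose by 3.02 (SE 0.054), and ENO2, ALDOC and HK2 changed by -2.70 (SE 0.058), -1.56 (SE 0.061) and -1.34 (SE 0.049). Of 22 cholesterol synthesis genes 10 rose and 8 fell, with a median of 0.03 (camera adjusted p = 0.412), and INSIG1, LSS and SQLE rose by 1.69 (SE 0.049), 1.42 (SE 0.050) and 1.28 (SE 0.050). With total counts only, the medians of the glycolysis and cholesterol lists were -0.41 and -0.39. Of 13 mitochondrially encoded genes 3 rose, 3 fell and 7 did not pass, with a median of -0.03, a mean of 0.01 and a camera direction of lower (adjusted p = 0.906), and their share of all counts was 3.75% ± 0.104 in parental and 2.73% ± 0.353 in knockout libraries (SD, n = 3). MT-ND3 changed by -0.19 (SE 0.051), while MT-ND6, MT-ND5 and MT-CYB changed by 0.24 (SE 0.059), 0.17 (SE 0.055) and 0.31 (SE 0.10), values that were below 0 with total counts only, where MT-ND5 passed as lower (adjusted p = 0.00777). The call of MT-CYB was lost without parental replicate 1 (0.38), 2 (0.30) or 3 (0.33), and that of MT-ND5 without parental replicate 1 (0.21) or 2 (0.16). Of 27 replication-dependent histone genes 9 fell, 5 rose and 13 did not pass, with a median of -0.18 (camera adjusted p = 0.576). H4C3, H2BC5 and H2BC9 changed by -2.02 (SE 0.12), -1.07 (SE 0.065) and -1.13 (SE 0.13), and H4C8 rose by 1.51 (SE 0.11). Histone genes are near-identical copies with few polyadenylated transcripts, so single members are uncertain, and their share of all counts was 0.0863% ± 0.00518 in parental and 0.0348% ± 0.00103 in knockout libraries (SD, n = 3). Of 30 neuronal and neuroendocrine genes 19 fell and 10 rose, with a median of -1.64 (camera adjusted p = 0.0752). The list passed without knockout replicate 2 (adjusted p = 0.0482) and with a term for the replicate number (adjusted p = 0.0452), within a range from 4.5e-05 to 0.754 over the settings tried. The neurofilament NEFM and the receptor GFRA2 changed by -5.97 (SE 0.067) and -6.63 (SE 0.078), and the adhesion molecules L1CAM and NCAM1 rose by 7.16 (SE 0.066) and 5.32 (SE 0.059). The numbers of risen and fallen genes adjusted over the list alone were 10 and 6, 9 and 9, 10 and 8, 2 and 1, 5 and 7, and 11 and 19 in the order of these lists.

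Along the chromosomes, neighbouring genes moved together in some regions. In 150 windows of 20 Mb (GRCh38), each with at least 20 protein-coding genes of at least 5 CPM, 17 window medians lay beyond 0.5 in log2 fold change relative to the median of all 11111 placed genes, 11 above and 6 below. On chromosome 11, the 115 genes from 1 to 20000000 had a median of 1.17, and 87.8% of them lay above the median of all placed genes. Among the genes named above, PARVA, DKK3 and ADM lie there, and SOX6, named below, moved against that window (-1.78). The 40 genes of chromosome 9 from 1 to 20000000, which include PDCD1LG2, had a median of 1.11, and the 23 of chromosome 3 from 60000001 to 80000000 had 1.03. Lower medians were found for the 52 genes of chromosome 13 from 40000001 to 60000000 (-0.81), and for the 77 genes of chromosome 5 from 160000001 to 180000000 (-0.78), which include NPM1, HNRNPAB, SLU7, HMMR and CCNG1. ELF1, in the former, rose. On chromosome 17 the 185 genes from 1 to 20000000, with MYH2 and SHISA6, and with SMG6 and CD68 against its direction (0.92 and 1.27), had a median of -0.66, and the 116 genes from 20000001 to 40000000, with RPL19, RPL23, TAF15, ALDOC and ASIC2, and with CCL2 against its direction (7.98), had -0.67. Of 199 genes named by rule, 32 lay in the 17 windows, and 23 of these moved the way of their window. Without the genes of these windows, a setting chosen after seeing the data, 18779 genes changed and 22 lists were called.

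**Figure D4:**
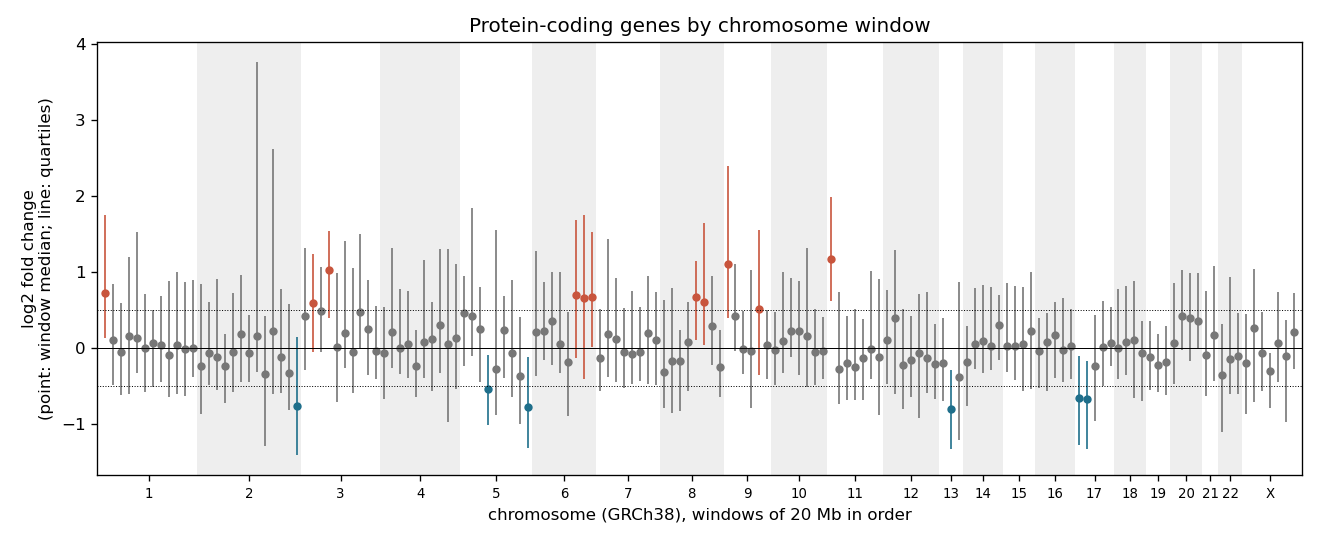
Median log2 fold change (point) and quartiles (line) of protein-coding genes of at least 5 CPM in 20 Mb windows in chromosome order (GRCh38), relative to the median of all placed genes. Dotted lines mark 0.5 in each direction; coloured windows lie beyond them, with the start of chromosome 11 highest at 1.17 and the window from 40000001 on chromosome 13 lowest at -0.81.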

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

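Subtracting the share kept by abundant genes and leaving out shifted windows were tests chosen after the result was seen. The count of changed genes, 21015, stayed between 20190 and 21414 when 1 library was left out and between 20141 and 23088 under other scalings, filters, tools and the subtraction (20951). It was 18779 without the genes of shifted windows. The exceptions were a filter of at least 1 CPM in 3 samples, where 13625 changed (6650 risen, 6975 fallen, 6034 beyond 1 in log2 fold change), fewer genes being tested, and the test against a log2 fold change of 1, where 9565 changed. Of the 21015, 19915 were also called by DESeq2 and 20880 by limma-voom, with the same sign. Scaling by total counts only also called 18917 of them, 18056 with the same sign and the others with the opposite sign. Upper quartile factors also called 19395, of which 19388 kept their sign. The number of called lists, 22, was 1 with an estimated correlation and 39 with fry, which asks another question, and 22 to 24 otherwise; no list that passed in either setting turned its direction relative to other genes. The median of epithelial markers, a called list, went below 0 with total counts only (-0.379, adjusted p = 0.00591), a replicate block (-0.026) and without parental replicate 2 (-0.055, adjusted p = 0.0257).

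The directions of 9 of 199 named genes reversed with total counts only: FLI1 (-0.04), MT-ND6 (-0.18), MT-ND5 (-0.25), MT-CYB (-0.10), ETV1 (-0.34), ERF (-0.37), ELF2 (-0.24), ELK1 (-0.064) and ETV5 (-0.019). Upper quartile factors reversed MT-ND5 (-0.03), ETV1 (-0.12), ERF (-0.15) and ELF2 (-0.021). Both scalings move the median of all genes down, by -0.42 and -0.20, and these rises are smaller than or close to that shift. Upper quartile factors also ended the calls of MT-ND6 and MT-CYB (adjusted p = 0.579 and 0.391), no filter and limma-voom that of MT-CYB (0.0921 and 0.0688), and the filter at 1 CPM that of MT-ND5 (0.0564). Rounding, thinning, the DESeq2 test and DESeq2 size factors changed no call of a named gene.

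With a replicate block, 20418 genes changed and 22 lists were called; the calls of p53 targets (adjusted p = 0.0714) and epithelial markers (0.310) were lost and those of neuronal and of FET and ETS genes (0.0452 each) gained, while no named gene changed its call. Libraries with the same number did not deviate together (correlations of -0.21, -0.04 and 0.04 over 13373 genes). For each number, at least 1 of its libraries correlated more with a library of another number (0.22, 0.22 and 0.18). That comparison decides nothing, as it sets the highest of several values against 1. Deviations of a gene also sum to 0 within a genotype, so a negative value for the same number forces a positive one elsewhere. As libraries with the same number did not deviate together, the numbers were not taken to pair the samples. The planned tests of transcripts and transcript usage, with their alternatives, were not run because the table holds counts per gene. With at least 301605666 counts in each library, depth limits mainly genes of a few counts.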

Other observations

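Tests of the floor between libraries other than that on genes of 1000 to 5000 counts, the shuffles of gene order, the tests on windows picked on every other gene and on windows that lose their shift, and the tests on FLI1 were chosen after the result was seen; SENCR was picked after its values were seen.

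Markers of other lineages moved gene by gene. Of 11 epithelial markers 5 rose and 4 fell, with a median log2 fold change of 0.04, -0.38 with total counts only and -0.055 without parental replicate 2, yet a camera call of higher (adjusted p = 0.0157, adjusted p = 0.326 with an estimated correlation, 0.310 with a term for the replicate number): KRT7, KRT8 and KRT18, keratins of simple epithelia, rose by 7.88 (SE 0.088), 5.35 (SE 0.077) and 5.22 (SE 0.063), and the tight junction protein OCLN by 1.89 (SE 0.062). Of 10 osteogenic markers 6 rose and 3 fell (median 1.00, camera adjusted p = 0.765); the bone regulator RUNX2 rose by 3.98 (SE 0.057) and ALPL by 1.49 (SE 0.050), while DLX5 changed by -6.38 (SE 0.068). Of 12 chondrogenic markers 4 rose and 6 fell (median -0.31, mean 0.09, camera adjusted p = 0.698). SOX5 and SOX6 changed by -1.88 (SE 0.068) and -1.78 (SE 0.062), while MATN3 rose by 3.73 (SE 0.095). Of 10 adipogenic markers 2 rose and 5 fell (median 0.11, -0.32 with total counts only, mean -0.22 and camera direction lower, adjusted p = 0.269). Lipoprotein lipase, LPL, and CEBPA changed by -6.65 (SE 0.11) and -3.40 (SE 0.12), while PPARG rose by 0.82 (SE 0.13). FABP4 rose by 6.88 (SE 0.66), to 0.147 CPM in knockout libraries. Of 9 skeletal muscle markers 2 rose and 4 fell (median -0.49, camera adjusted p = 0.257), with TNNT1 changing by -6.42 (SE 0.070) and TNNT2 rising by 4.95 (SE 0.10).

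Of 13 endothelial markers 5 rose and 6 fell (median -0.46, mean 0.84, camera adjusted p = 0.736); TEK and PECAM1 rose by 8.02 (SE 0.087) and 5.77 (SE 0.12), and EGFL7 and SOX18 changed by -1.60 (SE 0.058) and -2.74 (SE 0.13). Of 12 haematopoietic markers 5 rose and 5 fell (median 0.19, -0.23 with total counts only, mean -0.31, camera direction higher, adjusted p = 0.926). The leukocyte antigen PTPRC rose from 0.127 ± 0.0272 to 1.49 ± 0.157 CPM (SD, n = 3), while HBA1 changed by -3.46 (SE 0.21). Of 22 neural crest and stem cell markers 14 fell and 6 rose (median -1.18, camera adjusted p = 0.265): TFAP2B changed by -6.39 (SE 0.13), and SNAI2 and KLF4 rose by 4.63 (SE 0.060) and 5.68 (SE 0.11). Of 31 HOX genes 20 fell and 9 rose (median -0.98, camera adjusted p = 0.00718, adjusted p = 0.616 with an estimated correlation), among them HOXD13, HOXD8 and HOXD3 with -3.05 (SE 0.057), -2.08 (SE 0.050) and -2.46 (SE 0.062) and HOXC13 with -2.95 (SE 0.072). Adjusted over the list alone, the counts of these 9 lists were the same. By type, 83.5% of 16610 tested protein-coding genes changed, 62.8% of 2974 lincRNA genes, 60.5% of 2907 antisense genes and 51.5% of 1164 processed pseudogenes. Levels were not matched between types, so these shares do not show that the types responded differently.

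The lowest ratios between genotypes stopped near 0.617% of the parental count in knockout and 0.586% of the knockout count in parental libraries. A share that is the same for all genes, whether from exchanged reads or from foreign cells or RNA, is argued against in the parental libraries by SLC7A4, which at 5000 to 20000 counts lay at 0.354 times the floor (95% counting limit 0.478), the 1 such gene under 0.5 floors in that class; in the knockout libraries the lowest gene, CPNE4, lay at 0.857 floors (limit 1.05). Reads exchanged between libraries at shares that differ between genes stay open. In raw counts the shares of both directions had a quotient of 1.053, and among genes of 1000 to 5000 counts 0% of those within 2 floors lay under 0.5 floors. Scaled by library totals the shares were less alike, 0.674% in knockout and 0.536% in parental libraries. An exchange at 1 share for all genes would give that quotient and that 0%, so neither value bears on shares that differ between genes. A few cells or some RNA of the other genotype, at shares that differ between genes, cannot be told apart from exchanged reads. Floors within a genotype differed by at most 1.101 times, and the design holds no library without the other genotype beside it. Residual expression of the genes themselves cannot be told apart either: the log2 unit above the lowest ratio held 2.26 times the genes of the next unit, 4.69 times for falls (75 against 16) and 1.59 times for rises (92 against 58), and how residual levels spread over genes is not known. If exchanged reads or foreign RNA are the source, fold changes near -7 and 8 may understate the true ones, and a biological source that is alike in all these genes was not tested.

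Genes of 17 chromosome windows moved together, more than the highest of 10000 shuffles of gene order, 6 (permutation p = 1e-04, the smallest they can give). Without genes beyond 2 in log2 fold change the median over these windows, each signed by its own direction, was 0.599. Of the windows, 11 stayed beyond 0.5, which argues against a few strongly changed neighbours there. In the other 6 such neighbours cannot be told apart from a shared shift, and the window of chromosome 9 from 100000001 fell from 0.516 to -0.018. GC content, transcript length and expression level are argued against as the whole source, since they explained 1.76% of the variance and left 88.2% of the windows beyond 0.5. A copy number difference between the knockout and parental cultures is a candidate explanation, since in 19 windows picked on every other gene a median of 75% of the genes left (95% interval 65.8 to 79.3) lay on the side of their window. The quartile nearer to 0, signed in the same way and 0.102 as a median over the 17 windows, decides nothing, as the same genes picked them. Regional control of neighbouring genes by the fusion would give the same and stays open. Changes of modest size on chromosome 11 from 1, chromosome 5 from 160000001 or chromosome 17 from 1 could therefore have another source than the loss of EWS-FLI1 itself.

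FLI1 did not fall in the libraries labelled knockout. Swapped labels are argued against, since 88.1% of activated targets were lower there, and so are reads exchanged with parental libraries, since FLI1 lay at 144 times the floor. A candidate explanation is that the normal FLI1 gene, with its neighbours, is active in the knockout libraries: SENCR, which starts beside FLI1, had 1 count in each parental library and 129, 111 and 114 in the knockout libraries. A fusion transcript that is still made but no longer gives protein cannot be told apart from this with counts per gene. As the labels do not state strand, SENCR reads may also not be fully separated from FLI1 reads.

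The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 21015 changed genes and the highest other 0, and 22 called lists against 19, where every other split keeps part of the genotype difference on its sides. In both cases 1 split, the real one, gave a result as large.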
